A study of Mus musculus with 6 samples.

How the data were processed

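Total RNA of 6 HL-1 samples under palmitic acid, 3 with vector and 3 with ZNF593-AS, was sequenced on an Illumina instrument, per the labels. The deposited values are whole-number counts per gene, with no normalization, in 1 table with the exon length of each gene, per the file headers. CASAVA, cutadapt 1.2.1, Bowtie2, TopHat2 and the build GRCm38 are named in the submitters' processing notes, without roles. The counting tool, its strand and overlap settings and the annotation release are not given in the sources used here. Even counts were in excess, with 2160 to 2359 genes at a count of 2 and 365 to 492 genes at a count of 1 per library, so both mates of a pair appear to have been counted and a total stands for fewer fragments than it shows.

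The table held 49492 genes, of which 27135 had a count in any library. 26 gene names had been turned into dates and were restored from their coordinates. Genes were matched to the GENCODE M21 annotation of GRCm38 by coordinates and symbol (86.8%), and otherwise by coordinates or symbol alone, with 244 unmatched. Coordinates are those of the deposited table, counted from 1.

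How reads of overlapping genes were counted could not be settled. Among 2582 pairs of tested genes with overlapping exons on opposite strands, 20 had counts within 2% of each other in all 6 libraries, Zfp593 and E130218I03Rik among them. Of 31 such pairs that share at least 0.5 of both genes, 5 were within 2%. In all, 31.7% of the called genes overlapped another tested gene. Values of overlapping and antisense genes are therefore uncertain. For the genes named and the cardiac lists, the share of 50-base stretches of their transcripts found in transcripts of other genes was computed from GENCODE M21, and a high share makes a gene's value uncertain.

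Samples were grouped by title. No 2 libraries agreed within sampling noise (chi-square per gene of 10.8 or more on halved counts). Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 16473 genes and 99.97% of the counts of the library that lost most. Library sizes were scaled by TMM, and ZNF593-AS was tested against vector with edgeR 4.0.16 (robust dispersions, quasi-likelihood F test, 2-sided, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. The biological coefficient of variation was 7.69%. CPM values are counts per 1e6 of TMM-scaled library size with the SD over 3 libraries, and the SE of a log2 fold change is its size divided by the square root of the F statistic. Adjusted p-values of single genes are edgeR's throughout unless another tool is named.

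33 gene lists suited to heart muscle cells under lipid load, 6 of them cell type markers, were fixed before the data were examined, as were the groups, the tests, the naming rule and most of the alternatives listed below. The interferon-stimulated list was set as a main question from a recollection that the study group had worked on IRF3 signalling, which was not checked in any source here. The lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01 and again with an estimated correlation, and with fry, all adjusted over the 33 lists. With the preset correlation 11 lists passed. With an estimated correlation 0 passed and 5 had an unadjusted p under 0.05. The smallest adjusted p was then 0.0771, so no camera call held under that setting. The loss was not due to correlation alone. The nucleic acid sensing list had an estimated correlation of 0.0083, under the preset 0.01, yet its unadjusted camera p went from 1.11e-09 to 0.00347. A call lost under the estimate therefore does not show that correlated genes had produced it. In fry 9 lists passed. Members were counted as higher, lower or not passed over all genes, and adjusted over the list alone.

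The genes named are, by rule, the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and groups that did not overlap, the 5 most abundant called genes per direction, up to 3 called members per direction and list by smallest p (or the member with the smallest p where none was called), and Zfp593, Irf3, Hnrnpc, Ryr2 and Mfn2, the last 4 from a recollection, not checked here, of earlier work on this RNA. Genes with names of the form Gm plus a number, or ending in Rik or in -ps with or without a number, were skipped by name; biotype was not used, and Cxcl11 is annotated as a polymorphic pseudogene. Genes outside the rule are named where a partner gene, an exception or a short list of calls required it.

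The pipeline was tested on simulated data: in 5 simulations of 16230 to 16268 genes with 200 changed genes, 68.6% of the genes changed 1.5-fold and 86.5% of those changed 2-fold were called, and 7.61% of the calls were false, against a nominal 5%. The raised list passed camera in 5 simulations and an unchanged list in 0. Simulated genes were drawn independently of each other, so the preset correlation could not be tested this way. In the data the interferon-stimulated list had an estimated correlation of 0.609. As many simulated genes rose as fell, so scaling under an unequal balance of changes was not tested either.

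At library totals of 51470457 to 84547615, 1 CPM equals 50.6 counts or more in each library, or 25.3 fragments if both mates were counted. Intervals on low counts were computed on halved counts, rounded down, and limits from a count of 0 take 3 fragments of 2 counts; both cover counting error only. Alternatives were DESeq2 1.42.0 size factors or library totals in place of TMM, no filter, a mean of at least 1 CPM, the replicate number as a block, leaving out each library, DESeq2's Wald test, limma-voom and a log2 fold change threshold of 1. Halved counts and protein-coding genes alone were added after the data were seen. Sequence overlaps and tests of the closing section were computed with Python 3 libraries pandas, numpy and scipy.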

Results

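RNA was sequenced from HL-1 cells, a line derived from mouse atrial cardiomyocytes, kept under palmitic acid, a saturated fatty acid used in culture to model the lipid overload of heart muscle cells. 3 libraries came from cells given an empty vector and 3 from cells made to overexpress ZNF593-AS, a human long noncoding RNA transcribed from the strand opposite to ZNF593. The single comparison of the design was ZNF593-AS against vector, and it asks what this RNA does to gene expression in lipid-loaded cells. The 6 libraries include none without palmitic acid, so no change is ascribed to the fatty acid. The titles of all 3 treated libraries give ZNF593-AS, but the treatment fields of replicates 2 and 3 read ZNF594-AS and ZNF595-AS. The libraries were grouped by title, and the 3 treated libraries differed among themselves by a chi-square per gene of 10.8 to 12.8, against 11.03 to 13.4 among the vector libraries and 57.9 to 77.6 between the groups. Gene counts summed to 57191340, 51470457 and 73529088 in vector replicates 1 to 3 and to 84547615, 73667864 and 61042914 in ZNF593-AS replicates 1 to 3. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

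Interferon-stimulated genes, the antiviral and immune genes that cells switch on in response to interferon, were far lower in the ZNF593-AS libraries. Of 55 tested members of a list fixed before the data were examined, 53 fell, with a median log2 fold change of -3.15 over the list, or 8.90-fold. Mx1, an antiviral GTPase, went from 196 ± 16.1 CPM (SD, n = 3) with vector to 3.23 ± 0.165 CPM (SD, n = 3), a log2 fold change of -5.92 ± 0.09 (SE). Ifit2 went from 788 ± 77.3 to 35.8 ± 3.60 CPM (log2 fold change -4.46 ± 0.10), and Cmpk2, a mitochondrial nucleotide kinase, from 29.1 ± 1.82 to 0.594 ± 0.109 CPM (-5.60 ± 0.12). The most abundant gene of the list, Ifit3, fell from 3265 ± 216 to 124 ± 35.4 CPM. The 2 members that did not pass were Ifi27, at 21.1 ± 1.51 and 24.2 ± 1.06 CPM, and Ifi27l2a, at 5.44 ± 0.656 and 2.52 ± 1.12 CPM; both are named here because they were the exceptions. Adjusted over the list alone, 54 genes were lower and 1 was higher. The list passed limma's camera with a preset correlation (adjusted p = 2.65e-122), but not when the correlation was estimated (adjusted p = 0.0771 with an estimated correlation). In limma's fry test, which asks whether the list's own genes move one way, the adjusted p was 0.000349.

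**Figure D1:**
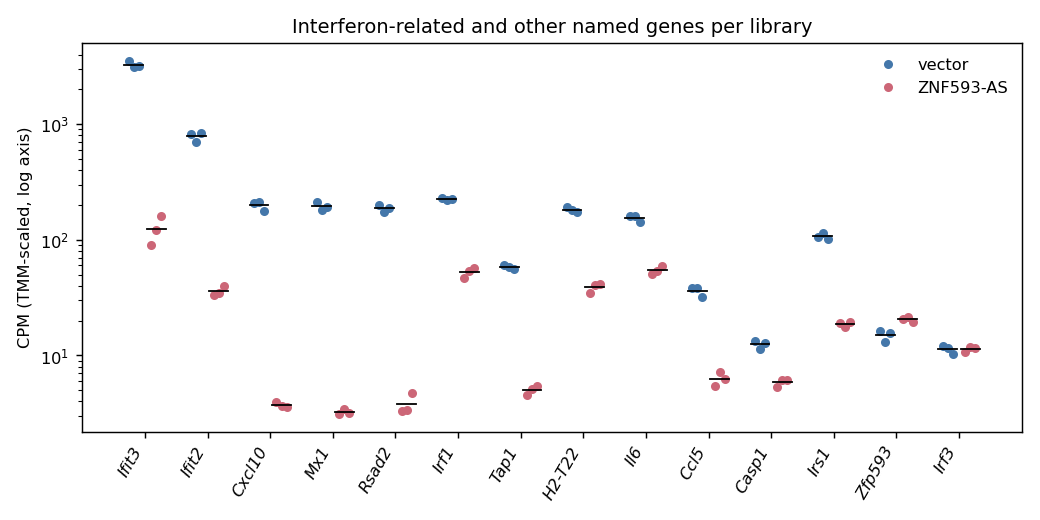
CPM on a log axis for 14 named genes in the 3 vector libraries (blue) and the 3 ZNF593-AS libraries (red); each point is a library and each bar a group mean. Ifit3 lay at 3265 CPM with vector and 124 CPM with ZNF593-AS, while Irf3 lay at 11.3 and 11.4 CPM.

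The 10 largest falls that met the naming rule began with Mx1 (GRCm38 chromosome 16, 97447035 to 97462907). They also held Cxcl10 (chromosome 5, 92346638 to 92348889), a chemokine that attracts T cells, which went from 199 ± 19.7 to 3.74 ± 0.174 CPM (log2 fold change -5.73 ± 0.09). Rsad2 (chromosome 12, 26442753 to 26456452), which encodes the antiviral enzyme viperin, went from 187 ± 12.9 to 3.81 ± 0.812 CPM (-5.63 ± 0.12). The others were Art3 (-5.81), Cmpk2 (-5.60), Trim30c (-5.46), Ifit3b (-5.27), Iigp1 (109 ± 7.69 to 3.47 ± 1.21 CPM), Slfn1 (-4.92) and Cxcl11 (-4.85). Art3 shares exon sequence with Cxcl10 on the opposite strand, so its count may hold reads of that gene. Ifit3 and Ifit3b share 51.2% and 45.0% of their 50-base stretches with other genes, so how reads were divided between them is uncertain.

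All 19 tested genes of MHC class I antigen presentation, the pathway that shows peptides at the cell surface, fell, with a median log2 fold change of -1.33. Tap1, a subunit of the peptide transporter, went from 58.2 ± 2.04 to 5.02 ± 0.435 CPM (-3.54 ± 0.08), Psmb9, an immunoproteasome subunit, from 5.93 ± 0.218 to 0.468 ± 0.0491 CPM (-3.67 ± 0.15), and H2-T22, a class I heavy chain, from 183 ± 9.94 to 39.0 ± 3.81 CPM (-2.23 ± 0.08). Tap1 and Psmb9 overlap on opposite strands, and H2-T22 overlaps A930015D03Rik and shares 34.5% of its 50-base stretches with other genes. All 19 also fell when adjusted over the list alone. The list passed camera (adjusted p = 5.76e-44), but not with an estimated correlation (adjusted p = 0.0771 with an estimated correlation).

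Of 22 tested genes of nucleic acid sensing and IRF3 signalling, 9 fell and 13 did not pass, with a median of -0.19 (camera adjusted p = 1.22e-08, adjusted p = 0.0771 with an estimated correlation). Those with the smallest p were Irf1, a transcription factor of the interferon response (226 ± 3.41 to 52.4 ± 4.99 CPM, log2 fold change -2.11 ± 0.07), Ifi204, a DNA sensor (1117 ± 33.6 to 344 ± 16.9 CPM, -1.70 ± 0.07), and Tlr3, a receptor for double-stranded RNA (6.98 ± 1.07 to 0.354 ± 0.199 CPM, -4.36 ± 0.24). Irf3, the transcription factor that starts interferon production, stood at 11.3 ± 0.945 and 11.4 ± 0.556 CPM (0.01 ± 0.09, edgeR adjusted p = 0.967). Adjusted over the list alone, 11 genes were lower. The mean log2 fold change of the list was -0.75, against the median of -0.19, so a minority of large falls carried much of its shift. Irf1 and Irf3 each overlap a gene on the opposite strand.

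Of 31 tested NF-kB targets, cytokines and chemokines, 10 fell, 1 rose and 20 did not pass, with a median of -0.21 (camera adjusted p = 3.73e-07, adjusted p = 0.328 with an estimated correlation). Besides Cxcl10, Ccl5 went from 36.2 ± 3.65 to 6.30 ± 0.868 CPM (-2.52 ± 0.10) and Il6, a cytokine of acute inflammation, from 155 to 54.5 CPM (-1.51 ± 0.07). Lcn2, an iron-binding secreted protein, rose from 6.82 ± 0.646 to 11.2 ± 1.90 CPM (0.71 ± 0.12). Adjusted over the list alone, 12 were lower and 1 was higher. The mean of this list was -0.51, against the median of -0.21, so here too a minority of large falls weighed most. Whether the sensing, NF-kB and inflammasome genes fell apart from the interferon response was not tested. In the list of 10 inflammasome and pyroptosis genes, 5 fell and 1 rose (median -0.30, camera adjusted p = 0.00296, adjusted p = 0.303 with an estimated correlation), and 5 and 2 did when adjusted over the list alone. The median was -0.12 with no filter and -0.46 with genes of at least 1 CPM or on halved counts. Casp1, the inflammatory caspase, went from 12.5 ± 1.08 to 5.88 ± 0.427 CPM (-1.09 ± 0.10), Casp4 from 79.7 ± 3.95 to 48.9 ± 1.86 CPM (-0.71 ± 0.06) and Il18, a cytokine matured by caspase cleavage, from 2.39 ± 0.0375 to 0.835 ± 0.153 CPM (-1.50 ± 0.18), while Nek7 rose (0.28 ± 0.06), a call that ended without vector replicate 1 or ZNF593-AS replicate 2. Of 27 apoptosis regulators, 4 fell, among them Bak1 (-0.37 ± 0.07) and Bid (-0.29 ± 0.06), and the list did not pass camera (adjusted p = 0.297) but passed fry (adjusted p = 0.0162). Adjusted over the list alone, 5 were lower and 1 was higher. Bid lost its call when library totals replaced the TMM factors.

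Of 29 genes of extracellular matrix and fibrosis, 12 fell and 2 rose (median -0.24, camera adjusted p = 4.74e-05, adjusted p = 0.531 with an estimated correlation), and 13 and 2 did when adjusted over the list alone. The fibrillar collagen gene Col1a1 went from 64.1 ± 1.61 to 46.8 ± 4.19 CPM (-0.45 ± 0.07), Timp2, a metalloproteinase inhibitor, from 193 ± 5.64 to 138 ± 9.42 CPM (-0.49 ± 0.07) and Thbs1 fell as well (-0.51 ± 0.09). Lox, which cross-links collagen, rose from 55.0 ± 2.28 to 80.3 ± 3.56 CPM (0.55 ± 0.06), as did Timp3 (0.52 ± 0.08). Of 30 DNA replication genes, 5 fell (median -0.14, camera adjusted p = 0.000165, adjusted p = 0.531 with an estimated correlation), among them the helicase subunit Mcm6 (-0.48 ± 0.06), the thymidylate synthase gene Tyms (-0.32 ± 0.06) and Mcm10 (-0.29 ± 0.06). Adjusted over the list alone, 9 were lower. Of 25 mitotic genes, 1 fell, the kinesin gene Cenpe (-0.28 ± 0.07), a call that ended under library totals and when vector replicate 1 or 2 or ZNF593-AS replicate 1 or 3 was left out, and the list did not pass camera (adjusted p = 0.437).

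In the list of 22 genes of triglyceride and fatty acid synthesis, 4 rose (median 0.10, camera adjusted p = 0.0081, adjusted p = 0.241 with an estimated correlation), as did 4 when adjusted over the list alone, and the median was 0.16 without vector replicate 3 and 0.07 without ZNF593-AS replicate 3. Scd2, a fatty acid desaturase, went from 49.8 ± 5.26 to 71.1 ± 3.14 CPM (0.51 ± 0.07), the elongase gene Elovl6 from 20.5 ± 1.11 to 26.6 ± 1.53 CPM (0.38 ± 0.07) and G0s2, a lipolysis inhibitor, from 29.1 ± 1.29 to 35.6 ± 0.602 CPM (0.29 ± 0.06). Of 25 genes of cholesterol synthesis and uptake, 3 rose (median 0.19, camera adjusted p = 0.00018, adjusted p = 0.241 with an estimated correlation), and 8 did when adjusted over the list alone. They were Pmvk (0.30 ± 0.07), Msmo1 (0.32 ± 0.07) and Fdft1 (0.22 ± 0.06), all enzymes of the pathway, and Fdft1 lost its call without any single library. Among 38 genes of fatty acid oxidation and PPAR targets, 4 rose and 1 fell, also when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.164, median 0.03) except without ZNF593-AS replicate 1 (adjusted p = 0.041, median 0.07). Fabp4, a fatty acid carrier, rose from 4.58 ± 0.485 to 6.96 ± 0.341 CPM (0.60 ± 0.11), as did the oxidation enzyme genes Acadm (0.30 ± 0.07) and Hadh (0.25 ± 0.06), while Plin2, which coats lipid droplets, fell from 1356 ± 83.7 to 1012 ± 31.0 CPM (-0.42 ± 0.07). The calls of Acadm and Hadh ended when ZNF593-AS replicate 3 was left out, and that of Hadh also without vector replicate 1 or ZNF593-AS replicate 2.

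Of 24 genes of insulin and IGF signalling, 3 fell and 1 rose, also when adjusted over the list alone, without a camera call (adjusted p = 0.298) but with a fry call (adjusted p = 0.0258). Irs1, the adaptor that couples the insulin receptor to its downstream kinases, went from 107 ± 6.57 to 18.7 ± 1.04 CPM (log2 fold change -2.52 ± 0.07, edgeR adjusted p = 2.67e-13). Irs1 spans 82233101 to 82291416 on chromosome 1, and Gm9747 lies inside it on the opposite strand at 82233112 to 82235933. Gm9747 went from 62.1 ± 5.31 to 11.2 ± 0.413 CPM (-2.47 ± 0.08), so the reads of both cannot be told apart there. Igfbp4 rose (0.37 ± 0.07) and Pik3r1 fell (-0.28 ± 0.08), a call that ended under library totals and without vector replicate 2 or 3 or ZNF593-AS replicate 1 or 3.

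None of the 39 genes of the unfolded protein and integrated stress response passed edgeR, where 14 were lower and 1 was higher at an unadjusted p under 0.05; DESeq2 called 2 lower and 1 higher and limma-voom called 0. The list's median was -0.12 (camera adjusted p = 0.0081, adjusted p = 0.673 with an estimated correlation), and the camera call ended under library totals (median -0.03, adjusted p = 0.141) and without ZNF593-AS replicate 2 (median -0.08, adjusted p = 0.240). Psat1, a serine synthesis enzyme, had the smallest p (-0.22 ± 0.07). Of 11 mitochondrially encoded protein genes 2 rose, mt-Cytb (0.50 ± 0.11) and mt-Nd3 (0.46 ± 0.11), and 3 did when adjusted over the list alone (median 0.31, camera adjusted p = 0.00358, adjusted p = 0.541 with an estimated correlation). The list's call ended without vector replicate 3, and its median was 0.17 without ZNF593-AS replicate 3 and 0.45 without vector replicate 1. Without either of these libraries the calls of mt-Cytb and mt-Nd3 ended as well. mt-Nd3 shares 98.0% of its 50-base stretches with other genes and mt-Cytb none. The nuclear copies Gm10925 and Gm28661 were at 4140 ± 639 and 2016 ± 501 CPM with vector. Mitochondrial reads may thus have been shared with near-identical genes, which was not tested. edgeR, DESeq2 and limma-voom called 0 of 37 nuclear-encoded respiratory chain genes and 0 of 23 genes of mitochondrial dynamics and biogenesis; at an unadjusted p under 0.05 there were 1 higher and 1 lower in the former and 3 higher and 1 lower in the latter. The camera adjusted p values were 0.887 and 0.671. Among these, Ndufb10 (0.17 ± 0.06) and Oma1 (0.46 ± 0.15) had the smallest p, and Mfn2, a mitochondrial fusion gene, was at 30.3 ± 3.41 and 27.9 ± 0.575 CPM (-0.12 ± 0.08). In the list of 29 genes headed NRF2 targets and antioxidant enzymes, Nqo1 rose (0.32 ± 0.07) and Keap1 (-0.43 ± 0.07) and Prdx1 (-0.34 ± 0.09) fell. The list did not pass camera (adjusted p = 0.697). It joins genes of unlike roles, so no direction of NRF2 activity is read from these calls. Without ZNF593-AS replicate 2 the calls of Nqo1 and Prdx1 ended.

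The cardiac genes that define atrial myocytes were close to absent in all 6 libraries. Myh6, the atrial myosin heavy chain, had 39 counts in total and Actc1, cardiac actin, 20. Nppa, the atrial natriuretic peptide gene, Sln and Kcna5 had no count, which allows up to 0.0149 CPM each over the 6 libraries if both mates of a pair were counted, counting error only. Ryr2, the calcium release channel, was at 0.144 ± 0.0508 CPM (SD, n = 6), under the filter for testing. By contrast Tnnt2, a cardiac troponin, was at 93.3 ± 8.02 CPM, Tpm1 at 1339 ± 88.0, Des at 530 ± 60.4, the transcription factor gene Gata4 at 9.39 ± 0.654 and Vim, a filament gene of mesenchymal cells, at 2023 ± 106 CPM. Of the 34 sarcomere genes in the table, 25 were under 1 CPM, as were 12 of 18 atrial and 28 of 45 calcium handling genes, against 2 of 38 nuclear-encoded respiratory chain genes. Among markers of other cell types, 10 of 20 fibroblast, 7 of 16 smooth muscle and pericyte, 18 of 20 endothelial and 17 of 22 macrophage genes were under 1 CPM. These genes, Ryr2 excepted, were chosen after their values were seen.

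**Figure D2:**
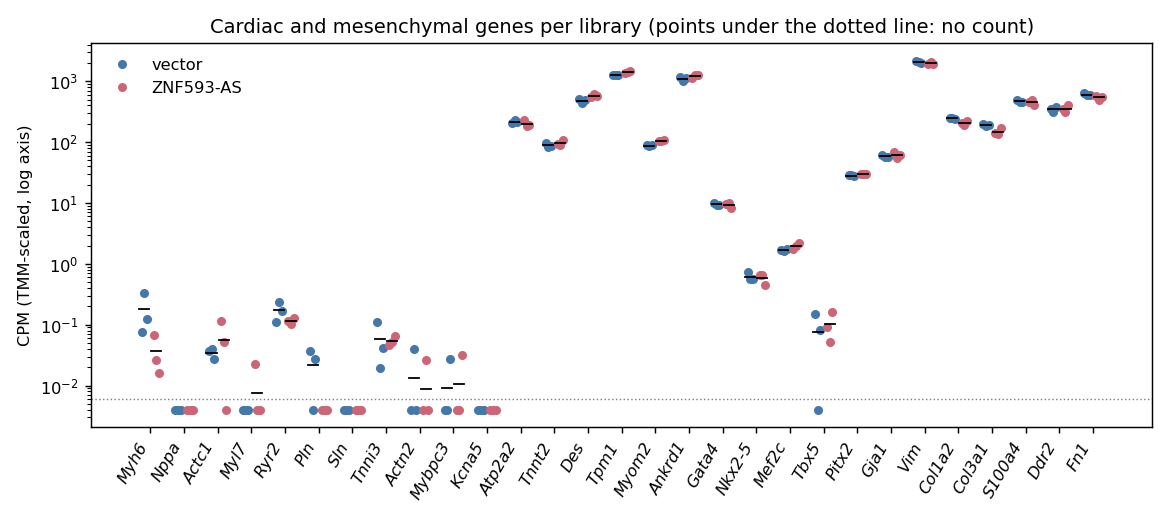
CPM on a log axis for 29 cardiac and mesenchymal genes in the 3 vector (blue) and 3 ZNF593-AS libraries (red); each point is a library, each bar a group mean, and points under the dotted line had no count. Nppa, Sln and Kcna5 had no count in any library, while Vim was at 2023 CPM.

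Among the 16 tested sarcomere genes Myom2 (0.27 ± 0.06) and Des (0.26 ± 0.07) rose and Mb fell (-2.01 ± 0.47), also when adjusted over the list alone (camera adjusted p = 0.493). The list passed camera with genes of at least 1 CPM alone (median 0.15, adjusted p = 0.0236, against a median of 0.03). Mb was at 0.358 ± 0.134 and 0.0871 ± 0.0267 CPM and overlaps Apol6 on the opposite strand, and its call ended without vector replicate 1 or ZNF593-AS replicate 3. Des lost its call without vector replicate 2 or 3 or ZNF593-AS replicate 2 or 3. Of 22 tested calcium handling and excitation genes, Camk2d (-0.29 ± 0.06), Itpr2 (-0.34 ± 0.07), Kcnj2 (-1.70 ± 0.42) and Asph (-0.25 ± 0.07) fell (camera adjusted p = 0.887). Of 9 tested atrial markers 1 fell, Bmp10, a growth factor of the atria, with 291 counts over the vector libraries and 2 over the ZNF593-AS libraries, a ratio of rates of 187 (95% exact binomial interval 32.8 to 7391 on halved counts, as both mates appear to be counted; counting error only). The camera adjusted p of the list was 0.881. Of 6 ventricular markers only Kcnj2 fell (camera adjusted p = 0.274), at 0.931, 0.434 and 0.415 CPM in vector replicates 1 to 3 and 0.137, 0.156 and 0.258 CPM in ZNF593-AS replicates 1 to 3. The call of Kcnj2 ended without vector replicate 1 or ZNF593-AS replicate 1 or 2, and that of Camk2d under library totals. In the list of 20 natriuretic peptide and hypertrophy genes edgeR and limma-voom called 0 and DESeq2 called 2 higher, with 3 higher and 2 lower at an unadjusted p under 0.05 in edgeR; Acta2, smooth muscle actin, had the smallest p (0.45 ± 0.13, adjusted p = 0.0583), and the camera adjusted p was 0.166, and 0.0477 without ZNF593-AS replicate 3.

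The remaining lists gave few calls. Of 30 immediate early and heat shock genes Dnajb1 (-0.40 ± 0.10), Hspa8 (-0.32 ± 0.09) and Hsph1 (-0.26 ± 0.07) fell and Dusp1 rose (0.37 ± 0.09; camera adjusted p = 0.912). Of 24 p53 targets Eda2r (-0.41 ± 0.06), Gtse1 (-0.41 ± 0.09) and Aen (-0.21 ± 0.06) fell and Rrm2b rose (0.27 ± 0.06; adjusted p = 0.309). Of 28 autophagy and lysosome genes Lamp2 fell (-0.46 ± 0.08; adjusted p = 0.154), and of 29 glycolysis and hypoxia genes Egln3 (0.36 ± 0.09) and Pfkm (0.33 ± 0.09) rose (adjusted p = 0.637). Of 16 fibroblast markers Col1a1, Col1a2 (-0.25 ± 0.07) and Col3a1 (-0.36 ± 0.08) fell and Pdgfra rose (0.39 ± 0.11; adjusted p = 0.695), of 13 smooth muscle and pericyte markers Des rose (adjusted p = 0.154, and 0.035 without ZNF593-AS replicate 1), and of 9 macrophage and leukocyte markers Ctss (-1.59 ± 0.22) and Cd74 (-0.60 ± 0.13) fell and Cd68 rose (0.46 ± 0.13; adjusted p = 0.493). edgeR, DESeq2 and limma-voom called 0 of 50 cytosolic ribosomal protein genes, 0 of 10 replication-dependent histone genes and 0 of 8 endothelial markers, with 1, 0 and 2 at an unadjusted p under 0.05 and camera adjusted p values of 0.112, 0.972 and 0.23. The ribosomal list, at a median of -0.06, passed camera without vector replicate 3 (median -0.12, adjusted p = 8.89e-06), ZNF593-AS replicate 1 (-0.08, 0.0358) or ZNF593-AS replicate 2 (-0.09, 0.0211). These calls used the preset correlation. Over all 6 libraries its estimated correlation was 0.697, with a camera adjusted p of 0.822 under that estimate and a fry adjusted p of 0.565. In these 3 lists, Rpl27 (-0.21 ± 0.09), Hist2h2bb (-0.55 ± 0.35) and Kdr (1.46 ± 0.55) had the smallest p. Hist2h2bb shares 53.6%, Hspa8 38.6% and Rpl27 23.5% of 50-base stretches with other genes, so their values are uncertain. Without vector replicate 1 the calls of Dnajb1, Hspa8, Hsph1, Dusp1, Aen, Rrm2b, Egln3, Pfkm, Col1a2, Pdgfra, Cd74 and Cd68 ended, and without ZNF593-AS replicate 2 that of Col3a1. Adjusted over the list alone, the counts differed for immediate early genes (4 lower, 2 higher), autophagy (2 lower, 1 higher), fibroblast (4 lower, 1 higher), smooth muscle (4 higher) and ventricular markers (2 lower). In 7 lists, none of which passed camera, the median, the mean and the direction of the test differed in sign. The fry test passed 9 lists, which besides apoptosis, insulin signalling and interferon-stimulated genes were MHC class I and nucleic acid sensing (adjusted p = 0.000349 each), inflammasome (0.00456), NF-kB targets (0.00845), triglyceride synthesis (0.012) and cholesterol synthesis (0.032). It did not pass DNA replication (0.0873), extracellular matrix (0.103), mitochondrially encoded (0.302) or unfolded protein response genes (0.317), which camera had called.

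**Figure D3:**
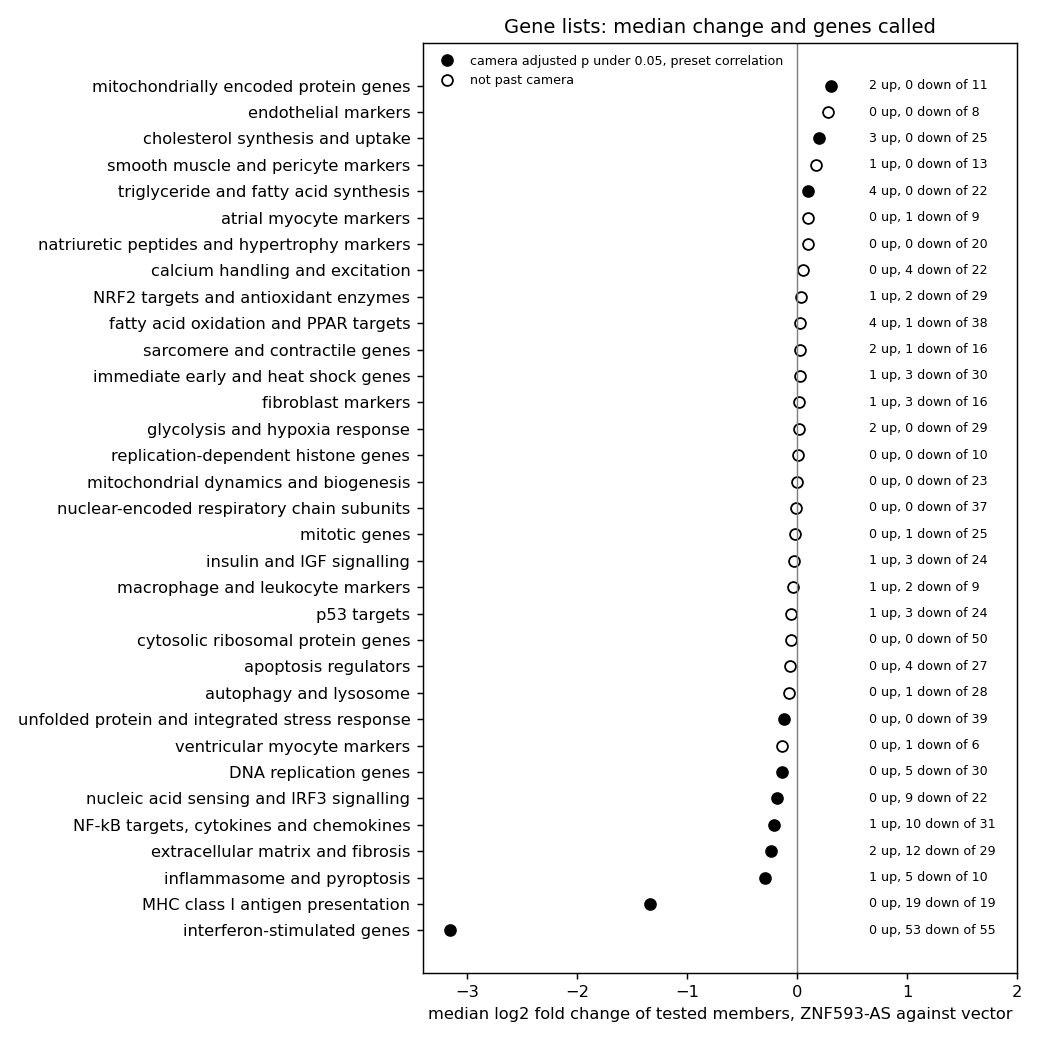
Median log2 fold change, ZNF593-AS against vector, of the tested members of 33 gene lists; filled points passed camera with a preset correlation, open points did not, and the text gives the genes called up and down of those tested. Interferon-stimulated genes had a median of -3.15 and MHC class I genes of -1.33, and the other medians lay between -0.30 and 0.31.

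Over all genes, 16473 were tested and 1383 (8.40%) passed edgeR's quasi-likelihood test at an adjusted p under 0.05, of which 1015 were lower and 368 higher. Falls were larger than rises: 426 genes were at least 2-fold lower and 21 at least 2-fold higher, 113 were at least 8-fold and 51 at least 16-fold lower, and the median fold was 1.68 among lower and 1.30 among higher calls. The groups did not overlap in 1377 of the called genes and in 4253 of all genes tested, where chance gives 10% for 3 against 3. The first principal component held 58.7% of the variance and separated the groups. The largest rises that met the naming rule were Atp6v0d2, a proton pump subunit (0.610 ± 0.116 to 1.52 ± 0.227 CPM, 1.32 ± 0.22), Palm3 (0.99), Mblac2 (0.97), Nptx1 (0.95), Kank4os (0.91), Il23a, a cytokine subunit (0.89), St6gal1 (0.87), Tmod1 (0.86), Tcea3 (0.84) and Gas1 (0.75). The most abundant higher genes besides mt-Cytb and Des were Neat1, a nuclear noncoding RNA (299 ± 10.7 to 427 ± 81.0 CPM), Grem1 (278 ± 16.6 to 351 ± 28.9 CPM) and Odc1 (258 ± 15.2 to 311 ± 17.7 CPM). The most abundant lower genes by mean CPM over the 6 libraries were Msn (2624 ± 134 to 2188 ± 49.9 CPM), Hspa8, Ubb (1969 ± 231 to 1559 ± 47.9 CPM), Ifit3 and Tpm3 (1328 ± 87.3 to 1120 ± 34.0 CPM). Without ZNF593-AS replicate 3 the calls of Palm3, Mblac2, Gas1, Msn, Hspa8, Ubb and Tpm3 ended, and without vector replicate 1 those of Neat1 and Odc1. Ubb, Odc1 and Tpm3 share 48.1%, 24.3% and 23.2% of their 50-base stretches with other genes. Palm3, St6gal1, Tmod1, Timp3, Thbs1, Keap1, Bak1, Bid, Nek7, Fdft1, Pfkm and Asph share exon bases with a gene on the opposite strand, so their values are uncertain too. The balance of calls depended on scaling: with library totals alone, 61.3% of calls were higher (1284 higher, 811 lower) against 26.6% with TMM factors, and the median log2 fold change of all genes was 0.10 against 0.01. List medians moved with it, to -0.05 for DNA replication, -0.10 for nucleic acid sensing, -0.12 for NF-kB targets, -0.15 for extracellular matrix and 0.19 for triglyceride and fatty acid synthesis, and all these lists still passed camera with the preset correlation. The count of higher genes fell to 138 without ZNF593-AS replicate 2 and to 170 without ZNF593-AS replicate 3, and was 209 and 234 without vector replicate 1 and 2.

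The human ZNF593-AS sequence was not among the features counted, so its overexpression was not measured here. The mouse gene named like its neighbour, Zfp593 (chromosome 4, 134243289 to 134245592, minus strand), rose by a log2 fold change of 0.46 ± 0.09 (edgeR adjusted p = 0.00186). E130218I03Rik, on the plus strand at 134243662 to 134245873, shares 1627 exon bases with Zfp593 and had nearly the same counts in each library, such as 870 for Zfp593 and 868 for E130218I03Rik in vector replicate 1 and 1819 and 1816 in ZNF593-AS replicate 1. The log2 fold change of E130218I03Rik was also 0.46 ± 0.09, so a change of either gene cannot be told from a change of the other. Reads of the human RNA that mapped to this locus would also have been counted there, which was not tested. Hnrnpc, an RNA-binding protein gene, was at 1234 ± 76.8 and 1176 ± 14.2 CPM (-0.07 ± 0.07, edgeR adjusted p = 0.648).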

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

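Halved counts and protein-coding genes alone were chosen after the data were seen. Of 97 named genes called, 60 kept the call under all alternatives that tested them, the fold threshold left aside. The other 37 lost it under at least 1 of these, and none turned direction. Of the 27 named genes below a log2 fold change of -1, only Mb and Kcnj2, both under 1 CPM, lost it where tested. Genes that an alternative left out were not counted as lost. Bmp10 (mean 0.81 CPM) was left out at a mean of at least 1 CPM, and Cxcl11 among protein-coding genes. The 1015 lower genes ranged from 811 (library totals) to 1111 (no filter) over the other settings and from 827 to 962 without single libraries, but were 426 at a log2 fold change of at least 1. The 368 higher genes were 1284 under library totals, 561 with no filter, as more genes are then tested, and 21 at a log2 fold change of at least 1; without single libraries they ranged from 138 to 394, with fewer samples. The cause of the other shifts was not tested, apart from the scaling weighed in the other observations. Genes called in common with an alternative never had opposite signs. The median of the interferon-stimulated list was -3.06 or lower under all 3 scalings, and its call ended only with an estimated correlation (median -3.15, adjusted p = 0.0771), when 0 of the 11 lists passed. The replicate numbers did not pair the libraries: same-numbered libraries' deviations from their group means correlated at -0.03, -0.03 and 0.05 across genes. With the replicate block, 334 genes were higher and 997 lower, and it ended the calls of single named genes such as Aen and Fdft1. Depth limits little here, but cannot separate overlapping genes.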

Other observations

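The tests of the splits, scaling, leukocytes, empty vector, depth, culture identity, GC content or length and mean CPM were chosen after the results they bear on were seen, as were the library values in the next paragraph.

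Gene families grouped by symbol stem were tested for enrichment among the called genes (437 families with at least 5 tested members, Fisher's exact test, 874 tests). They share members with the fixed lists, such as Ifi204 and Col1a1, so they are not independent of those lists. Among lower genes 15 families passed and among higher genes 0. All 11 tested Gbp genes, guanylate-binding proteins that act against pathogens inside cells, fell, as did 6 of 6 Oas genes, 8 of 9 Slfn genes, 15 of 19 Ifi genes and 6 of 8 Apol genes (adjusted p = 5.27e-11, 1.6e-05, 7.54e-07, 6.14e-12 and 0.000331). Outside these, 12 of 46 Trim genes, 7 of 16 Serpinb genes and 9 of 31 Col genes fell (adjusted p = 0.00321, 0.00323 and 0.00954). Members of a family can share reads, so their falls are not independent. A stem can also join unlike genes, as the 8 Slfn genes hold Slfn5os, named as an opposite-strand transcript. The genes lower at least 2-fold also lay close together: 58.5% had another such gene within 100 kb, against a highest value of 17.6% in 10000 random sets of as many tested genes, and 40.0% against 12.6% among genes with no exon overlap. The random sets took no account of families, whose members can be neighbours. Whether the closeness goes beyond the falls of whole families was therefore not tested.

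The interferon-stimulated list took 1.54% to 1.62% of all counts in the vector libraries and 0.148%, 0.183% and 0.215% in ZNF593-AS replicates 1 to 3. Of its 53 called genes, 47 were highest, among the 3 ZNF593-AS libraries, in replicate 3, and 47 were lowest in replicate 1. The list's median log2 level against the vector mean was -3.55, -3.22 and -2.81 in these replicates. Ifnb1, the interferon beta gene, had 12, 22 and 22 counts in the vector libraries and 0, 0 and 4 in the ZNF593-AS libraries, a ratio of rates of 17.9 (95% exact binomial interval 4.53 to 155 on halved counts, counting error only).

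The fall of interferon-stimulated genes did not come from scaling, since the highest list median under TMM, DESeq2 size factors and library totals was -3.06. Leukocytes in the vector cultures are argued against by 9 transcripts that are abundant in leukocytes. Their summed level was 3.42 to 3.81 CPM with vector and 3.25 to 3.82 CPM with ZNF593-AS, a largest ratio of 1.17. They were picked from the 22 macrophage and leukocyte markers as transcripts that interferon does not need. Of the markers left out, Ctss and Cd74 fell and Cd68 rose. A stronger interferon response to the empty vector, or another difference in how the arms were handled, cannot be told apart from an effect of the RNA, because 0 libraries came from cells without a vector or from a second control. An action of ZNF593-AS upstream of interferon stays open and was not tested. For the 1383 calls, 1 of the 10 splits of the 6 libraries into 3 and 3 gave as many (the real one), the highest other gave 0 in edgeR with at most 897 genes at an unadjusted p under 0.05, and 10 splits are too few for a share under 0.05.

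The near absence of cardiac genes was not a matter of depth, since 1 CPM equals 50.6 counts in the shallowest library, or 25.3 fragments if both mates were counted, which is under the bound of 30 set for counts but far from 0. Loss of reads to near-identical copies is argued against because 92.0% of the sarcomere genes under 1 CPM share under 10% of their 50-base stretches with other genes. Cultures of another cell type, or a line that had lost its cardiac identity before or under palmitic acid, cannot be told apart, as 0 libraries came from cells without palmitic acid. Both stay candidate explanations, and no biological explanation was tested.

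A candidate explanation for the many genes higher under library totals is that counts freed by the interferon genes raise the share of all others. The interferon list and all genes lower at least 2-fold were then left out of the totals. The median log2 fold change of all genes went from 0.102 to 0.0599. That is just under the upper of the 2 bounds, 0.03 and 0.06, set before this test was run. It met neither bound, so the test could not tell. Other genes called lower by less than 2-fold stayed in the totals, so how much of the shift freed counts explain was not settled. A trend with GC content or exon length was first tested among the genes not called lower, with a bound of 0.1 set before the result, and Spearman's rho was 0.0394 and -0.0980, just inside it. Because a set that leaves out called genes excludes nothing, all tested genes were then used, with a margin of 2 standard errors, and rho was 0.0508 and -0.106, the larger 0.106 in size, so a weak trend remains open. Genes are not independent here, and a larger trend, with mean CPM (rho -0.222 over all tested genes), for which no bound was set, also remains open.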
